A study of Mus musculus with 9 samples.

How the data were processed

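RNA from D2.OR mouse mammary tumor cells grown in 3D culture was measured on 9 Affymetrix arrays, 3 per group. Sample titles put the arrays in fibrillar collagen, non-fibrillar collagen and Matrigel groups, each numbered 1 to 3. The Matrigel group rests on its titles alone: the growth label of those 3 arrays repeats the wording used for non-fibrillar collagen I, and the series design names the collagen conditions only. The Matrigel arrays also carry later accession numbers than the other 6, so any batch that goes with this cannot be told apart from the Matrigel group. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

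The deposited values are log2 expression per probe set, made by the authors with Affymetrix Power Tools and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes the probes of the arrays in a run and summarizes them per probe set, which pulls the arrays towards one distribution and can hide a change shared by most genes. Versions, settings and whether all 9 arrays were normalized in one run are not given in the sources used here. The table held 35512 probe sets with values from 2.11 to 14.08 log2 units and column medians from 5.98 to 6.05. Across all probe sets Pearson's r was 0.994 to 0.996 within groups (9 pairs) and 0.992 to 0.996 between groups (27 pairs); genes are not independent replicates in these correlations. No arrays were duplicates, since the closest pair differed by 0.127 log2 units on average. Background readings and detection calls were not used here, and the number of arrays limits the precision.

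The platform annotation gave 21789 probe sets a single gene symbol, 1621 several, and left 12102 unlisted; the last kinds stayed unnamed and out of the gene tests. Gene identifiers matched a current gene table for 21698 of the single-symbol probe sets, and 0 symbols were renamed. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 9 arrays was used, which left 19938 genes. No filter was set on dim probe sets and no value was rescaled.

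Differences were fitted on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The collagen groups were compared with their own 6 arrays; each comparison with Matrigel used one fit of all 9 arrays, with a mean per group. Errors of log2 differences are limma's standard errors (SE) with n = 3 arrays per group. A fold is 2 to the power of the log2 difference. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over 36 lists per comparison. The lists covered cell cycle, matrix and adhesion, signalling, mammary lineage, inflammation, metabolism, stress and markers of other cell types, and 733 of their 783 entries were measured. Because the preset correlation is low, each list was also tested with a correlation estimated from the arrays, and with fry, which asks whether the genes of a list move one way and does not set them against other genes. With the estimated correlation 0 lists passed in any comparison.

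Groups, tests, gene lists and alternatives were fixed before the data were examined, as was the rule for named genes. That rule took, per comparison, the 8 largest positive and 8 largest negative log2 differences among genes that passed and whose groups did not overlap, skipping predicted models, and the 3 members with the smallest p of each list described. Genes named outside the rule are said to be so. Alternatives were the arrays in the fit, the replicate number as a block, quantile normalization again, centring on array medians, filters on dim genes, other handling of several probe sets, a trended robust prior, array weights, stricter thresholds, other list tests and leaving out each array.

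Deviations from the group means were correlated between arrays of the same number to see whether the numbers pair the arrays, a correlation across genes. For fibrillar and non-fibrillar collagen, r was 0.221, 0.143 and 0.242 for replicates 1, 2 and 3, all above 0.1. The numbers were therefore taken to pair these arrays, a pairing that comes from the data and not from a label. The main collagen fit had been fixed without a block and was kept, so it ignores this pairing. A fit with replicate number as a block is given as an alternative. For the Matrigel comparisons not every pair passed 0.1.

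The scripts were tested on simulated data with 19938 genes, of which 100 were changed by a log2 size of 0.5 and 100 by 1. In the simulation of the collagen comparison 82% of the smaller and 96% of the larger changes were called, and 5.32% of calls were false. The figures were 86%, 100% and 3.63% for fibrillar collagen against Matrigel, and 84%, 100% and 5.15% for non-fibrillar collagen against Matrigel. The simulated shift of 1 list was called each time, with 0 of the other lists. Every gene was simulated independently of the others. The simulation therefore cannot show how often camera with the preset correlation calls lists falsely, or how the share of false calls changes, when genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.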

Results

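Gene expression was measured in D2.OR cells, a mouse mammary tumor line known for long dormancy after it spreads, grown in 3D culture in fibrillar collagen I, in non-fibrillar collagen I or, by their titles, in Matrigel, a basement membrane extract. Each group held 3 arrays with log2 RMA values. The title of the series links fibrillar collagen to the protection from mammary cancer that follows pregnancy, and the collagen comparison asks how the form of the collagen changes expression in these cells.

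The groups lay apart in a principal component analysis of 19938 genes. The first component held 40.1% of the variance and placed the non-fibrillar arrays at -13.1 ± 0.39 (SD, n = 3), the fibrillar arrays at 1.32 ± 1.42 and the Matrigel arrays at 11.8 ± 1.73. The second held 18.2% and separated the fibrillar arrays, at 9.35 ± 1.83, from the non-fibrillar arrays at -3.78 ± 1.19 and the Matrigel arrays at -5.57 ± 3.17.

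**Figure D1:**
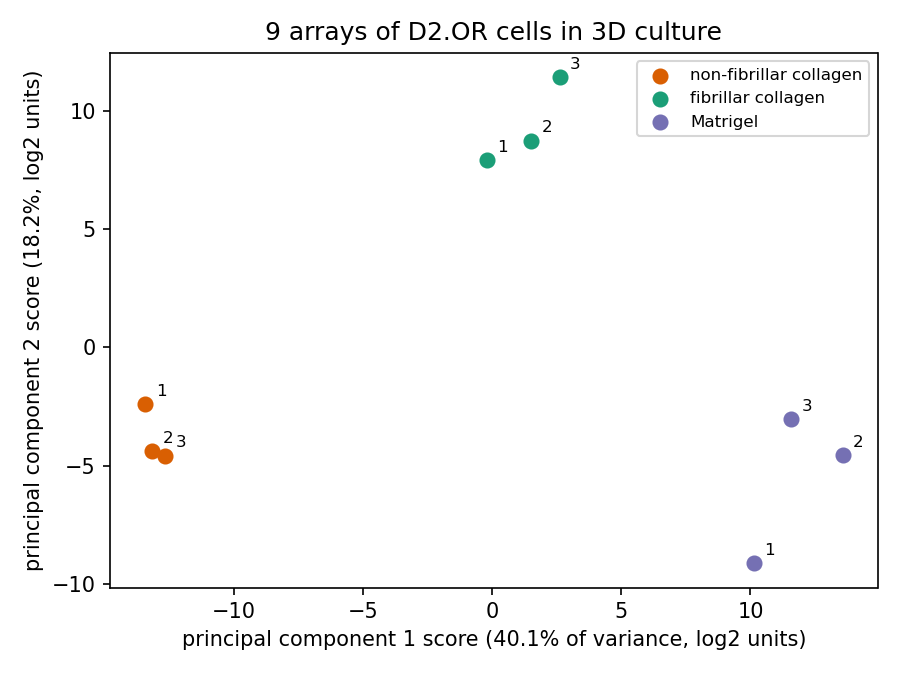
Scores of the 9 arrays on principal components 1 (40.1% of variance) and 2 (18.2%), in log2 units, numbered by replicate and coloured by group. The fibrillar arrays lie between the other groups on the first component and above both on the second.

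Cells in fibrillar collagen had lower expression of interferon-induced genes than cells in non-fibrillar collagen, and higher expression of basement membrane, fatty acid synthesis and lysosomal genes. As lists these passed camera with the preset correlation but not with an estimated one (interferon and fatty acid synthesis adjusted p = 0.207 with an estimated correlation, basement membrane adjusted p = 0.329 and lysosome adjusted p = 0.672). With fry all but the lysosome list passed (adjusted p = 0.0090, 0.0042 and 0.012 for interferon, fatty acid synthesis and basement membrane). The largest decrease was in Usp18, which removes the interferon-induced modifier ISG15 from proteins, at 2.52-fold lower (log2 -1.33 ± 0.134 SE, adjusted p = 0.0070). The largest increase was in Fam102a, at 2.19-fold higher (log2 1.13 ± 0.051, adjusted p = 0.0041). Atp8b1, a phospholipid flippase, was 2.07-fold higher (1.05 ± 0.091, adjusted p = 0.0053), and Abca1, which exports cholesterol from cells, 1.99-fold higher (0.99 ± 0.071, adjusted p = 0.0041). The next largest increases were in the aminopeptidase Anpep (0.95 ± 0.094), the thyroid hormone-activating deiodinase Dio2 (0.87 ± 0.078), pyruvate carboxylase Pcx (0.87 ± 0.147), the glycosyltransferase Large2 (0.84 ± 0.049) and the imprinted gene Peg3 (0.84 ± 0.083), with adjusted p from 0.0041 to 0.025. Besides Usp18, the largest decreases were in the interferon-induced Ifit3 (-1.17 ± 0.143), the insulin-like growth factor binding protein Igfbp4 (-1.11 ± 0.083), the cytokine Il1a (-1.03 ± 0.195), Ifit1 (-0.95 ± 0.115), the interferon regulator Irf7 (-0.94 ± 0.083), the phosphatase Ptpn22 (-0.94 ± 0.127) and the ecto-nucleotidase Nt5e (-0.92 ± 0.063), with adjusted p from 0.0041 to 0.033.

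**Figure D2:**
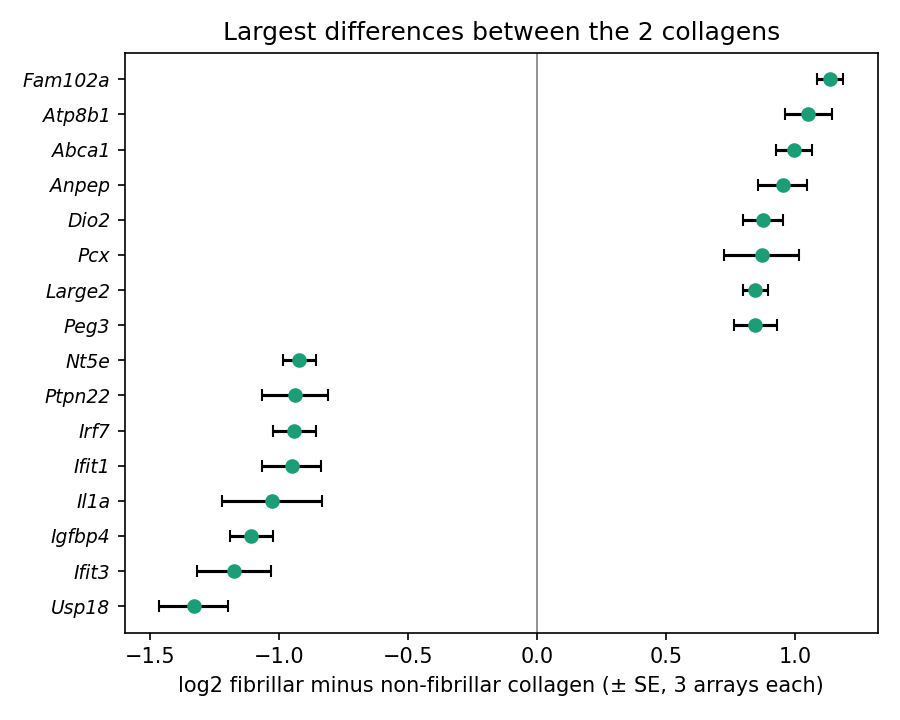
Log2 difference between fibrillar and non-fibrillar collagen (x axis) for the 8 largest increases and 8 largest decreases; points are differences of group means and bars are limma's standard errors, 3 arrays per group. Differences run from -1.33 for Usp18 to 1.13 for Fam102a.

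In all, 541 genes were higher and 736 lower in fibrillar than in non-fibrillar collagen (limma, 4316 at an unadjusted threshold of 0.05). Most differences were small: the median size among called genes was 0.30 log2 units, and 6 called genes reached 2-fold, 2 higher and 4 lower. The groups did not overlap for 5024 genes, 25.2% of those tested, where chance gives 10%. The share of calls that were higher was 42.4%, against 51.1% after quantile normalization again (640 higher, 612 lower) and 30.3% after centring on array medians (421 higher, 968 lower). The number of calls depended on each array: it was 569, 217 or 150 without fibrillar replicate 1, 2 or 3, and 327, 197 or 406 without non-fibrillar replicate 1, 2 or 3. None of these fits used the pairing by replicate number. With that number as a block, 970 of the 1277 main calls (76.0%) were kept. Of the 16 genes with the largest differences, 9 were called whichever array was left out. The call was lost without fibrillar replicate 3 for Peg3, without that array or non-fibrillar replicate 2 for Usp18, and without non-fibrillar replicate 2 or 3 for Ifit3. Ifit1 lost it without fibrillar replicate 2 or any non-fibrillar array, Ptpn22 without any array but fibrillar replicate 1 and non-fibrillar replicate 3, Il1a without any array but fibrillar replicate 1, and Pcx without any array but non-fibrillar replicate 3. Over all refits adjusted p reached 0.056 for Peg3 and Usp18, 0.066 for Ifit3, 0.065 for Ifit1, 0.077 for Ptpn22, 0.124 for Il1a and 0.110 for Pcx.

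Of 26 measured genes of the interferon response, 15 were lower in fibrillar collagen, 0 were higher and 11 did not pass; 21 were lower when adjusted over the list alone. The median difference was -0.38 log2 units (camera adjusted p = 2.1e-16; adjusted p = 0.207 with an estimated correlation). The members with the smallest p were the guanylate-binding protein Gbp3, 1.80-fold lower (-0.85 ± 0.067), Irf7, and the oligoadenylate synthetase Oas1a, 1.55-fold lower (-0.63 ± 0.061, adjusted p = 0.0067; its call was lost without fibrillar replicate 3). Probe sets of the Ifit, Oas and Gbp families may read related copies, so single members of these families are uncertain.

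Cell cycle lists were lower in fibrillar collagen. Of 27 genes of DNA replication and the G1/S transition, 9 were lower, 0 higher and 18 did not pass, and 17 were lower when adjusted over the list alone. Its median was -0.18 (camera adjusted p = 1.6e-10; adjusted p = 0.329 with an estimated correlation). Examples were the clamp loader subunit Rfc4 (-0.48 ± 0.049, 1.39-fold lower), the histone mRNA-binding Slbp (-0.39 ± 0.047) and thymidylate synthase Tyms (-0.37 ± 0.047). Of 27 mitosis genes, only Cdk1 (-0.23 ± 0.032, adjusted p = 0.016) and Bub1 (-0.34 ± 0.072, adjusted p = 0.045) passed, both lower, while Ncapg was at -0.24 ± 0.059 (adjusted p = 0.066); 5 were lower when adjusted over the list alone. The list median was -0.10 (camera adjusted p = 5.3e-04; adjusted p = 0.672 with an estimated correlation and 0.217 with fry). In each same-numbered pair the mitosis mean was lower in fibrillar collagen, at 0.147, 0.024 and -0.045 log2 units for replicates 1, 2 and 3 against 0.174, 0.164 and 0.102, relative to the mean of all arrays. Cdk1 and Bub1 each lost the call without any array but fibrillar replicate 1, and Cdk1 also after quantile normalization again.

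Matrix genes were tested by class, and the classes were not compared with each other. Of 19 basement membrane genes, 5 were higher in fibrillar collagen, 0 lower and 14 did not pass, with 7 higher when adjusted over the list alone. The median was 0.12 (camera adjusted p = 7.6e-05; adjusted p = 0.329 with an estimated correlation). The laminin chains Lamb2 (0.54 ± 0.038, 1.45-fold) and Lama5 (0.46 ± 0.043, 1.38-fold) and the proteoglycan perlecan, Hspg2 (0.51 ± 0.041, 1.43-fold), were higher, and none of the 3 lost its call when an array was left out. Of 22 TGF-beta response genes, 4 were higher, 0 lower and 18 did not pass, and 7 were higher and 1 lower when adjusted over the list alone. Members had a median of 0.08 (camera adjusted p = 0.0070; adjusted p = 0.329 with an estimated correlation). They included the latent TGF-beta binding protein Ltbp2 (0.63 ± 0.052, 1.55-fold), the ligand Tgfb1 (0.29 ± 0.040) and the differentiation inhibitor Id3 (0.49 ± 0.10). Fibrillar collagens and their assembly proteins did not pass as a list (adjusted p = 0.366; 3 of 26 higher and 1 lower, the same when adjusted over the list alone): Col5a3 was higher (0.26 ± 0.036), fibronectin Fn1 was at 0.23 ± 0.040 (adjusted p = 0.029, and 0.0501 with replicate number as a block), and tenascin Tnc was lower (-0.33 ± 0.061).

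Genes for contact with the matrix went both ways. Of 20 integrins and collagen receptors, 3 were higher and 2 lower, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.166). Itga2, the alpha chain of a collagen-binding integrin, was 1.59-fold lower in fibrillar collagen (-0.67 ± 0.045, adjusted p = 0.0041), as was the syndecan Sdc1 (-0.24 ± 0.039), while Itgav was higher (0.27 ± 0.044). Among 25 matrix proteases and inhibitors, 5 were higher and 1 lower, and 7 and 4 when adjusted over the list alone (camera adjusted p = 0.899, with a median of -0.0087 and a mean of 0.034): the protease inhibitor Timp1 was lower (-0.42 ± 0.038), and Timp2 (0.26 ± 0.035) and the membrane-bound protease Mmp14 (0.31 ± 0.050) were higher. Of 18 YAP and TAZ targets, 2 were higher and 2 lower, and 8 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.281). Ankrd1, a classical target of this pathway, was 1.64-fold lower (-0.72 ± 0.044), and Asap1 (0.39 ± 0.047) and Tgfb2 (0.46 ± 0.072) were higher.

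Metabolic lists also differed. Of 16 fatty acid synthesis genes, 5 were higher in fibrillar collagen, 0 lower and 11 did not pass, and 11 were higher when adjusted over the list alone. This list had a median of 0.13 (camera adjusted p = 2.0e-07; adjusted p = 0.207 with an estimated correlation). Fatty acid synthase Fasn was 1.39-fold higher (0.48 ± 0.041), the lipogenic transcription factor Srebf1 1.35-fold higher (0.43 ± 0.042) and acetyl-CoA carboxylase Acaca 1.23-fold higher (0.30 ± 0.035). Of 28 oxidative phosphorylation genes, 11 were lower, 0 higher and 17 did not pass, with 16 lower when adjusted over the list alone. Their median was -0.13 (camera adjusted p = 1.6e-10; adjusted p = 0.207 with an estimated correlation). The complex I subunits Ndufa1 (-0.37 ± 0.053), Ndufa2 (-0.38 ± 0.056) and Ndufb5 (-0.27 ± 0.040) had the smallest p. Of 25 lysosome and autophagy genes, 6 were higher, 1 lower and 18 did not pass, and 10 were higher and 1 lower when adjusted over the list alone. The list as a whole had a median of 0.088 (camera adjusted p = 0.0028; adjusted p = 0.672 with an estimated correlation and 0.0505 with fry). The cholesterol transporter Npc1 was 1.54-fold higher (0.62 ± 0.059) and the lysosomal protein Ctsa 1.20-fold higher (0.26 ± 0.042), whereas Atg5, needed to form autophagosomes, was 1.30-fold lower (-0.37 ± 0.063).

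Of 23 hypoxia response genes only Higd1a passed, 1.30-fold lower in fibrillar collagen (-0.38 ± 0.083, adjusted p = 0.049), and 0 passed when adjusted over the list alone. The list median was -0.13 (camera adjusted p = 0.0024; adjusted p = 0.672 with an estimated correlation and 0.313 with fry). Without non-fibrillar replicate 3 its median was -0.080 and it did not pass (adjusted p = 0.0736; range over its alternatives 1.9e-06 to 0.672). In each same-numbered pair the list mean was lower in fibrillar collagen, at -0.062, -0.048 and 0.080 for replicates 1 to 3 against 0.122, 0.0074 and 0.362, and replicate 3 was the highest of both groups. P4ha1 was at -0.23 ± 0.080 (adjusted p = 0.163), and Bnip3 at -0.53 ± 0.191 (adjusted p = 0.170, and 0.0272 with replicate number as a block). Of 20 ribosomal protein genes, Rps14 alone passed (-0.23 ± 0.036, lower), with Rps3 at -0.18 ± 0.040 and Rpl7 at -0.24 ± 0.059 (adjusted p = 0.053 and 0.069), and 5 were lower when adjusted over the list alone. Together they had a median of -0.094 (camera adjusted p = 1.3e-05; adjusted p = 0.207 with an estimated correlation). Rps14 lost its call after quantile normalization again and without any array but fibrillar replicate 1. Of 22 ribosome biogenesis and MYC target genes, 4 were lower, 0 higher and 18 did not pass, with 7 lower and 1 higher when adjusted over the list alone. Its median was -0.13 (camera adjusted p = 6.6e-05; adjusted p = 0.329 with an estimated correlation). Examples were ornithine decarboxylase Odc1 (-0.28 ± 0.044), dyskerin Dkc1 (-0.20 ± 0.035, adjusted p = 0.028, and 0.0552 with replicate number as a block) and Rrp9 (-0.25 ± 0.050, adjusted p = 0.039, and 0.0581 with the block). Higd1a and Odc1 lost their calls when all probe sets of a gene were averaged (ranges over their alternatives 0.017 to 0.150 and 0.0053 to 0.0819).

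Markers of other cell types did not pass as lists. Among 15 macrophage markers 1 was higher and 1 lower (camera adjusted p = 0.708): Cd68, which is also a general lysosomal glycoprotein, was 1.78-fold higher in fibrillar collagen (0.83 ± 0.081), Cd14 was lower (-0.37 ± 0.079), and Tyrobp was at 0.12 ± 0.068 (adjusted p = 0.349). Adjusted p was 0.152 for adipocyte, 0.394 for fibroblast and 0.708 for lymphocyte markers. Endothelial markers were at 0.0526, and at 0.0332 with replicate number as a block. The block also brought in glycolysis (0.0754 without it, 0.0332 with it), endoplasmic reticulum chaperones (0.0526 and 0.0229) and the Notch pathway (0.0754 and 0.0416; 0.0271 with fry). Wnt targets (0.0627), cholesterol synthesis and NF-kB targets (both 0.166), NRF2 targets (0.394), immediate early, mesenchymal and luminal mammary genes (each 0.407), epithelial junctions and basal mammary genes (both 0.459), cell cycle brakes (0.701), p53 targets and the integrated stress response (both 0.708) and actin and SRF targets (0.894) did not pass. Over the refits that left out 1 array, 21 of the 57 named genes called in this comparison never lost the call; Higd1a, Fn1, Itgav, Ndufa2, Dkc1 and Cd14 lost it whichever array was left out. Besides those already given, Tyms, Col5a3, Tnc, Mmp14, Sdc1, Id3, Ndufa1, Ndufb5, Ctsa, Atg5, Odc1 and Rrp9 lost it in 5 of the 6 refits and Timp2, Tgfb1 and Tgfb2 in 4. Slbp and Acaca lost it in 3, Asap1 in 2 and Rfc4 in 1.

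**Figure D3:**
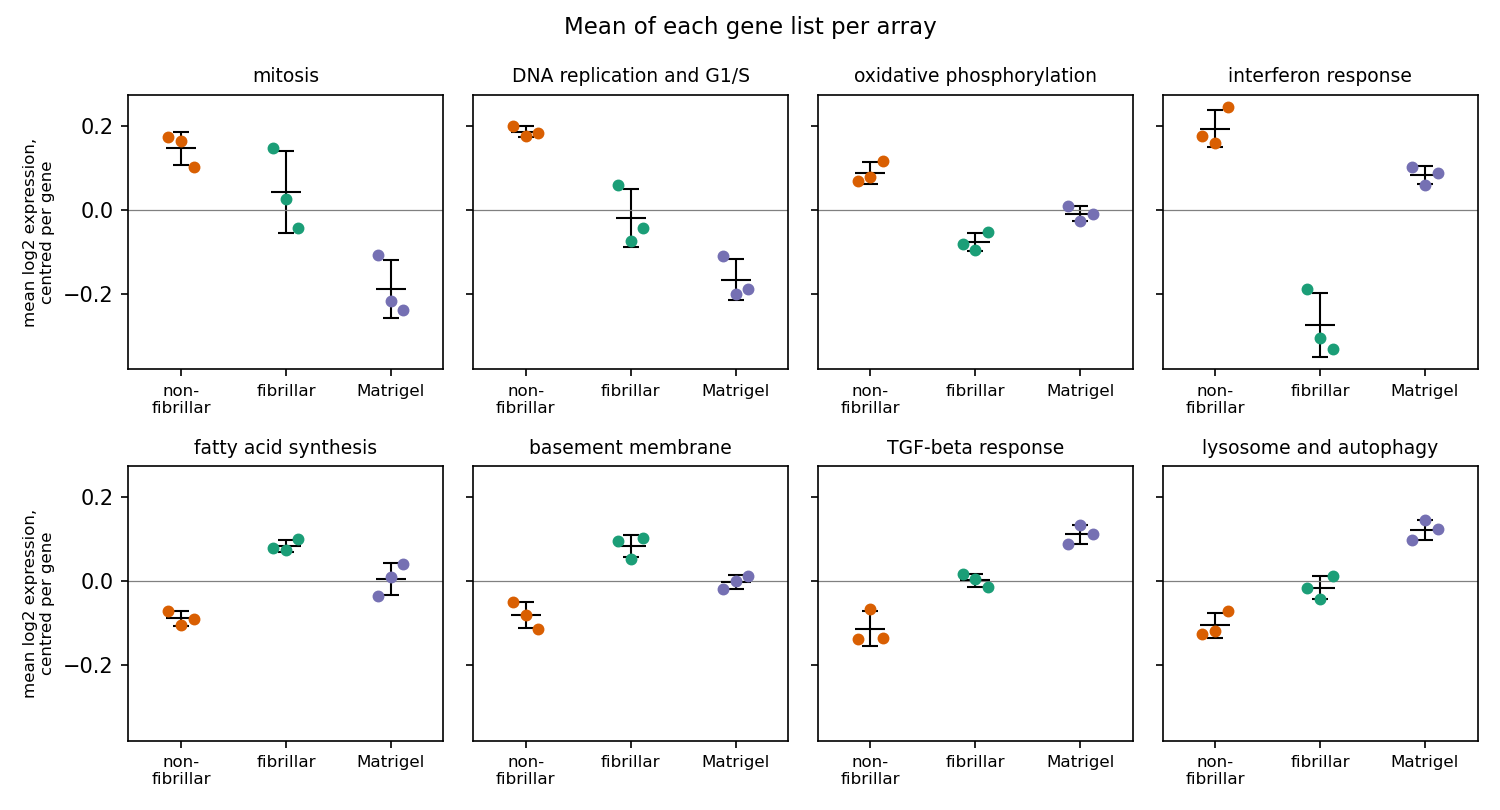
Mean log2 expression of 8 gene lists per array (y axis, each gene centred on its mean over the 9 arrays), by group; horizontal lines are group means and bars are ± 1 SD over 3 arrays. Interferon and oxidative phosphorylation genes are lowest, and fatty acid synthesis and basement membrane genes highest, in fibrillar collagen; mitosis genes fall from non-fibrillar over fibrillar collagen to Matrigel, where the collagen groups overlap but each fibrillar array lies below the non-fibrillar array of its number.

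Against Matrigel, cells in fibrillar collagen had higher expression of cell cycle genes and lower expression of interferon-induced, lysosomal and antioxidant genes. As lists these passed camera with the preset correlation but not with an estimated one (mitosis and lysosome adjusted p = 0.251 with an estimated correlation, DNA replication adjusted p = 0.275, interferon and NRF2 adjusted p = 0.122). With fry all of them passed (adjusted p from 0.0027 to 0.0184). The largest increases were in Il1a (log2 0.94 ± 0.209 SE, 1.92-fold, adjusted p = 0.039), the keratin Krt7 (0.90 ± 0.039, 1.87-fold, adjusted p = 8.7e-06), the urokinase Plau (0.86 ± 0.101), Large2 (0.84 ± 0.048), Tnc (0.75 ± 0.056), Nt5e (0.75 ± 0.077), the G protein regulator Rgs16 (0.72 ± 0.062) and Itga2 (0.68 ± 0.052). The largest decreases were in the selenium carrier Selenop (-1.78 ± 0.123, 3.43-fold lower, adjusted p = 1.7e-04), the serpin Serpinb9e (-1.64 ± 0.116, 3.11-fold lower), monoglyceride lipase Mgll (-1.48 ± 0.218), Parm1 (-1.45 ± 0.059), the protease Bace2 (-1.43 ± 0.143), Plxdc1 (-1.22 ± 0.119), the angiopoietin Angpt1 (-0.998 ± 0.128) and Ifit3 (-0.97 ± 0.138). Serpinb9e has close paralogs and is uncertain as a single gene.

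In this comparison 289 genes were higher and 473 lower (limma, 3606 at an unadjusted threshold of 0.05), with a median size of 0.31 log2 units; 6 called genes reached 2-fold, all lower. The groups did not overlap for 4059 genes (20.4%, chance 10%). The share of calls that were higher was 37.9%, against 50.5% after quantile normalization again (373 higher, 366 lower). Calls numbered 434, 419 or 462 without fibrillar replicate 1, 2 or 3 and 513, 353 or 488 without Matrigel replicate 1, 2 or 3. Of the 16 largest differences only Il1a lost its call, without fibrillar replicate 1 or 2, any non-fibrillar array, or Matrigel replicate 2 or 3 (range over its alternatives 0.0022 to 0.138).

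Of 27 mitosis genes, 8 were higher in fibrillar collagen than in Matrigel and 0 lower, with 21 higher when adjusted over the list alone. The median was 0.23 (camera adjusted p = 1.9e-15; adjusted p = 0.251 with an estimated correlation). Topoisomerase Top2a (0.31 ± 0.046), the transcription factor Foxm1 (0.29 ± 0.047) and the kinase Aurkb (0.27 ± 0.045) had the smallest p. Top2a lost its call when its probe sets were averaged (range over its alternatives 0.0025 to 0.203). Of 27 DNA replication genes, 7 were higher and 0 lower, 10 higher when adjusted over the list alone (median 0.13, camera adjusted p = 2.0e-07; adjusted p = 0.275 with an estimated correlation). They included Rrm1 (0.29 ± 0.040), Cdc6 (0.35 ± 0.066) and Uhrf1 (0.33 ± 0.063). Ribosome biogenesis and MYC targets had 1 of 22 genes higher, Cad (0.26 ± 0.044), with Mybbp1a at 0.16 ± 0.042 and Nop56 at 0.17 ± 0.054 (adjusted p = 0.070 and 0.130), and 2 higher when adjusted over the list alone. That list (median 0.048, camera adjusted p = 0.011; adjusted p = 0.316 with an estimated correlation and 0.0772 with fry) did not pass without fibrillar replicate 1 (median 0.024, adjusted p = 0.0985; range over its alternatives 0.0024 to 0.316).

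Interferon response genes were lower than in Matrigel too: 11 of 26 were lower and 0 higher, 19 lower when adjusted over the list alone. Members had a median of -0.28 (camera adjusted p = 1.9e-15; adjusted p = 0.122 with an estimated correlation). Gbp3 (-0.85 ± 0.077), Irf7 (-0.66 ± 0.082) and Ifit1 (-0.73 ± 0.101) had the smallest p. Lysosome and autophagy genes were lower, 5 of 25 with 0 higher and 14 lower when adjusted over the list alone (median -0.12, camera adjusted p = 9.8e-09; adjusted p = 0.251 with an estimated correlation). Gabarapl1 (-0.41 ± 0.045), Npc2 (-0.40 ± 0.066) and Hexa (-0.30 ± 0.054) had the smallest p. NRF2 targets, an antioxidant program, were lower in 6 of 17 with 0 higher; adjusted over the list alone 6 were lower and 1 higher. This list had a median of -0.098 (camera adjusted p = 1.0e-05; adjusted p = 0.122 with an estimated correlation). Heme oxygenase Hmox1 was lower (-0.59 ± 0.068), the cystine transporter Slc7a11 1.28-fold lower (-0.36 ± 0.057) and Gclm 1.20-fold lower (-0.27 ± 0.044). TGF-beta response genes were lower in 4 of 22 with 0 higher, and in 8 with 1 higher when adjusted over the list alone (median -0.076, camera adjusted p = 0.0018; adjusted p = 0.251 with an estimated correlation). Inhba (-0.50 ± 0.060), Id2 (-0.32 ± 0.046) and Klf10 (-0.28 ± 0.043) led them. Of 28 oxidative phosphorylation genes 1 was lower, Ndufb8 (-0.25 ± 0.053), and 4 when adjusted over the list alone. Ndufb5 was at -0.19 ± 0.051 and Cox6c at -0.14 ± 0.038 (adjusted p = 0.078 and 0.079; list median -0.052, camera adjusted p = 0.0012, adjusted p = 0.275 with an estimated correlation). Ndufb8 lost its call in 10 of 19 alternatives, 7 of them with 1 array left out (range over its alternatives 0.014 to 0.0905).

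Several lists were higher in fibrillar collagen than in Matrigel with few single genes called. Basement membrane genes had 2 of 19 higher and 0 lower (median 0.078, camera adjusted p = 0.0018; adjusted p = 0.275 with an estimated correlation). Lama5 (0.32 ± 0.044) and Lamb1 (0.27 ± 0.052) were higher, with Lamc1 at 0.19 ± 0.052 (adjusted p = 0.082), and 4 were higher and 1 lower when adjusted over the list alone. Epithelial junction and keratin genes had 2 of 26 higher, Krt7 and Krt18 (0.23 ± 0.040), with Epcam at 0.16 ± 0.051 (adjusted p = 0.125), and the same number when adjusted over the list alone. Their median was 0.056 (camera adjusted p = 0.0052; adjusted p = 0.251 with an estimated correlation). The integrated stress response had 4 of 22 higher and 1 lower, 13 higher and 1 lower when adjusted over the list alone (median 0.19, camera adjusted p = 1.6e-06; adjusted p = 0.122 with an estimated correlation). Asparagine synthetase Asns (0.35 ± 0.039) and the folate enzyme Mthfd2 (0.36 ± 0.063) were higher and Slc7a11 lower. Fatty acid synthesis had 1 of 16 higher, Fasn (0.38 ± 0.050), with Elovl6 at 0.15 ± 0.036 and Acaca at 0.17 ± 0.049 (adjusted p = 0.057 and 0.092), and 8 higher and 1 lower when adjusted over the list alone. This list (median 0.12, camera adjusted p = 0.011; adjusted p = 0.316 with an estimated correlation) did not pass without Matrigel replicate 1 (adjusted p = 0.0626; range over its alternatives 0.0039 to 0.316).

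Cholesterol synthesis had 2 of 19 genes higher in fibrillar collagen than in Matrigel, Pmvk (0.24 ± 0.048) and Msmo1 (0.18 ± 0.042), with Fdft1 at 0.12 ± 0.036 (adjusted p = 0.119), and the same number when adjusted over the list alone. The list as a whole had a median of 0.098 (camera adjusted p = 0.0051; adjusted p = 0.251 with an estimated correlation). Glycolysis had 1 of 18 higher, Pfkl (0.29 ± 0.066), and 3 when adjusted over the list alone, with Slc2a1 at 0.36 ± 0.097 and Slc16a3 at 0.40 ± 0.106 (adjusted p = 0.073 and 0.074). The list (median 0.082, camera adjusted p = 0.0098; adjusted p = 0.553 with an estimated correlation and 0.235 with fry) did not pass without fibrillar replicate 3 (adjusted p = 0.0537) or Matrigel replicate 1 (adjusted p = 0.0705; range over its alternatives 0.0017 to 0.553). The hypoxia list was higher (median 0.17, camera adjusted p = 0.0045; adjusted p = 0.558 with an estimated correlation and 0.313 with fry), although the only 1 of 23 members that passed, the carbonic anhydrase Car12, was lower (-0.36 ± 0.050). Stc2 was at 0.24 ± 0.061 (adjusted p = 0.063), and 2 were higher and 1 lower when adjusted over the list alone. Of the lists that did not pass, cell cycle brakes and adipocyte markers came closest (both adjusted p = 0.0507), passing in 5 and 7 of 14 alternatives. Integrins and collagen receptors did not pass (adjusted p = 0.0683, and in 3 of 14 alternatives they did). Of these 20 genes, 4 were higher in fibrillar collagen, among them Itga2, and 2 lower, Sdc1 (-0.41 ± 0.041) and Itgb8 (-0.41 ± 0.091), both named outside the rule. YAP and TAZ targets (adjusted p = 0.265) and matrix proteases (adjusted p = 0.837, with a median of -0.035 and a mean of 0.016) did not pass either. Of the 46 named genes called in this comparison, 35 never lost the call when an array was left out. Besides Il1a and Ndufb8, Msmo1 lost it in 8 of 9 such refits, Pfkl in 6, Pmvk, Cdc6 and Uhrf1 in 4, Lamb1 and Hexa in 3, Mthfd2 in 2 and Krt18 in 1. Msmo1 lost it in 11 of all 19 alternatives, Pfkl in 8 and Pmvk in 6.

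The non-fibrillar collagen and Matrigel groups differed most. Cells in non-fibrillar collagen had higher expression of cell cycle, hypoxia and ribosome biogenesis genes and lower expression of lysosomal, TGF-beta response and antioxidant genes. As lists these passed camera with the preset correlation but not with an estimated one (hypoxia adjusted p = 0.369 with an estimated correlation, mitosis adjusted p = 0.215 and the others adjusted p = 0.142). With fry all of them passed (adjusted p = 0.0338 for hypoxia and at most 0.00225 for the others). The largest increases were in Il1a (log2 1.97 ± 0.209 SE, 3.91-fold, adjusted p = 3.2e-04), Nt5e (1.67 ± 0.077, 3.18-fold, adjusted p = 4.3e-06), Itga2 (1.35 ± 0.052, 2.54-fold, adjusted p = 1.5e-06), Igfbp4 (1.24 ± 0.081), Plau (1.22 ± 0.101), Rgs16 (1.20 ± 0.062), Krt7 (1.20 ± 0.039) and the secreted protein Wfdc2 (1.11 ± 0.043). The largest decreases were in Mgll (-2.18 ± 0.218, 4.54-fold lower, adjusted p = 2.2e-04), Selenop (-1.84 ± 0.123, 3.59-fold), Parm1 (-1.84 ± 0.059, 3.57-fold), Plxdc1 (-1.77 ± 0.119), Atp8b1 (-1.73 ± 0.107), Bace2 (-1.72 ± 0.143), Sytl2 (-1.60 ± 0.089) and Pcx (-1.53 ± 0.127). None of these 16 genes lost its call when any array was left out.

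Here 1345 genes were higher and 1410 lower (limma, 5088 at an unadjusted threshold of 0.05), with a median size of 0.29 log2 units; 13 called genes were at least 2-fold higher and 37 at least 2-fold lower. The groups did not overlap for 5661 genes (28.4%, chance 10%). The share of calls that were higher was 48.8%, against 62.8% after centring on array medians (1841 higher, 1092 lower). Without Matrigel replicate 2 calls fell to 1814.

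Of 27 DNA replication genes, 24 were higher in non-fibrillar collagen than in Matrigel, 0 lower and 3 did not pass; adjusted over the list alone 25 were higher and 1 lower. Together they had a median of 0.37 (camera adjusted p = 2.3e-17; adjusted p = 0.142 with an estimated correlation). The ribonucleotide reductase subunit Rrm1 (0.48 ± 0.040), Cdc45 (0.41 ± 0.044) and the helicase subunit Mcm7 (0.43 ± 0.047) had the smallest p. Of 27 mitosis genes, 20 were higher and 0 lower, 25 higher when adjusted over the list alone (median 0.33, camera adjusted p = 1.8e-16; adjusted p = 0.215 with an estimated correlation). Kif20a (0.39 ± 0.041), Top2a (0.43 ± 0.046) and Ncapg (0.51 ± 0.058) led them. Ribosome biogenesis and MYC targets were higher in 9 of 22 with 0 lower, 15 when adjusted over the list alone (median 0.19, camera adjusted p = 4.1e-08; adjusted p = 0.142 with an estimated correlation). Odc1 (0.34 ± 0.043), Dkc1 (0.29 ± 0.048) and Mybbp1a (0.21 ± 0.042) were the first of these. Ribosomal proteins were higher in 6 of 20 with 0 lower, 7 when adjusted over the list alone, among them Rps3 (0.29 ± 0.040), Rpl7 (0.30 ± 0.057) and Rps14 (0.24 ± 0.053). Their list (median 0.11, camera adjusted p = 8.2e-05; adjusted p = 0.142 with an estimated correlation) did not pass after quantile normalization again (adjusted p = 0.0611). Without Matrigel replicate 2 Rps14 lost its call (range over its alternatives 0.0030 to 0.0549).

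Hypoxia response genes were higher in 13 of 23 and lower in 1, 14 and 1 when adjusted over the list alone. Its median was 0.29 (camera adjusted p = 2.6e-06; adjusted p = 0.369 with an estimated correlation). Higd1a (0.48 ± 0.082) and the glucose transporter Slc2a1 (0.57 ± 0.097, 1.48-fold) were higher and Car12 lower (-0.41 ± 0.050). Non-fibrillar replicate 3 had the highest list means, at 0.362 for hypoxia against 0.122 and 0.0074 for replicates 1 and 2, and at 0.201 for glycolysis against 0.086 and -0.029. Replicate 3 was the highest of the fibrillar arrays too, at 0.080 and 0.072. Without it the list medians were 0.204 and 0.112, and both lists still passed with the preset correlation. Glycolysis genes were higher in 6 of 18 and lower in 1, 8 and 1 when adjusted over the list alone (median 0.17, camera adjusted p = 4.6e-04; adjusted p = 0.457 with an estimated correlation). They included the lactate transporter Slc16a3 (0.69 ± 0.106, 1.61-fold) and Pfkl (0.41 ± 0.066). The integrated stress response was higher in 7 of 22 and lower in 2, 11 and 2 when adjusted over the list alone (median 0.17, camera adjusted p = 1.9e-04; adjusted p = 0.142 with an estimated correlation). Cth, which makes cysteine, was 1.87-fold higher (0.90 ± 0.069) and Asns 1.31-fold higher (0.39 ± 0.039), while Slc7a11 was lower (-0.48 ± 0.057). Cholesterol synthesis had 7 of 19 higher and 1 lower, 10 and 2 when adjusted over the list alone, with Msmo1 (0.39 ± 0.042), Pmvk (0.44 ± 0.048) and Idi1 (0.27 ± 0.046). Its list (median 0.12, camera adjusted p = 0.0041; adjusted p = 0.215 with an estimated correlation) did not pass after quantile normalization again (adjusted p = 0.0872). Oxidative phosphorylation had 6 of 28 higher and 0 lower, and the same number when adjusted over the list alone, with Ndufa4 (0.28 ± 0.052), Sdhb (0.24 ± 0.046) and Uqcrq (0.19 ± 0.045) first. That list (median 0.084, camera adjusted p = 1.6e-04; adjusted p = 0.215 with an estimated correlation) also did not pass after quantile normalization again (adjusted p = 0.0657), and Uqcrq lost its call there and without non-fibrillar replicate 2 or Matrigel replicate 2 or 3 (range over its alternatives 0.0092 to 0.0756).

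Endoplasmic reticulum chaperones were higher in 8 of 20 and lower in 1, 9 and 3 when adjusted over the list alone. The median was 0.13 (camera adjusted p = 0.0099; adjusted p = 0.487 with an estimated correlation, and 0.143 after quantile normalization again). Sdf2l1 (0.46 ± 0.058) and Pdia4 (0.26 ± 0.042) were higher and Sel1l lower (-0.26 ± 0.040). Pdia4 lost its call when its probe sets were averaged (range over its alternatives 6.3e-04 to 0.529). Immediate early genes were higher in 4 of 24 and lower in 2, 6 and 2 when adjusted over the list alone (median 0.075, camera adjusted p = 0.026; adjusted p = 0.221 with an estimated correlation). Ier2 (0.49 ± 0.052) and Ier3 (0.48 ± 0.054) were higher and the phosphatase Dusp4 lower (-0.53 ± 0.058). They did not pass after quantile normalization again (adjusted p = 0.0759), with the dimmest genes left out (0.0526), or without non-fibrillar replicate 3 (0.0662) or Matrigel replicate 1 (0.0626). Interferon response genes were higher in 4 of 26 with 0 lower, 5 when adjusted over the list alone. Members had a median of 0.067 (camera adjusted p = 0.0494; adjusted p = 0.487 with an estimated correlation and 0.0789 with fry). Oas1a (0.50 ± 0.065), Isg20 (0.43 ± 0.075) and Usp18 (0.62 ± 0.119) were higher, but the list did not pass after quantile normalization again (0.0846), with the dimmest genes left out (0.0904), or without non-fibrillar replicate 3 (0.166), Matrigel replicate 1 (0.0580) or Matrigel replicate 2 (0.107).

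Of 25 lysosome and autophagy genes, 17 were lower in non-fibrillar collagen than in Matrigel and 0 higher, 18 lower and 1 higher when adjusted over the list alone. This list had a median of -0.23 (camera adjusted p = 2.7e-10; adjusted p = 0.142 with an estimated correlation). Hexa (-0.57 ± 0.054), Gabarapl1 (-0.46 ± 0.045) and the proton pump subunit Atp6v0d1 (-0.34 ± 0.041) had the smallest p. TGF-beta response genes were lower in 11 of 22 and higher in 2, 13 and 3 when adjusted over the list alone (median -0.20, camera adjusted p = 5.6e-06; adjusted p = 0.142 with an estimated correlation). Ltbp2 was 2.01-fold lower (-1.01 ± 0.060), Id3 1.75-fold (-0.80 ± 0.086) and Id2 1.42-fold (-0.51 ± 0.046). NRF2 targets were lower in 6 of 17 with 0 higher, 7 when adjusted over the list alone (median -0.11, camera adjusted p = 2.7e-04; adjusted p = 0.142 with an estimated correlation). Hmox1 was 2.03-fold lower (-1.02 ± 0.068), the glutathione transferase Gstm1 2.12-fold lower (-1.09 ± 0.104), and Slc7a11 was again among them. Fatty acid synthesis genes were lower in 4 of 16 with 0 higher, 6 when adjusted over the list alone (median -0.10, camera adjusted p = 0.0020; adjusted p = 0.227 with an estimated correlation). Srebf1 (-0.28 ± 0.044), Acly (-0.20 ± 0.039) and Scd1 (-0.21 ± 0.047) were lower. Scd1 lost its call without Matrigel replicate 2 or 3 (range over its alternatives 0.0032 to 0.0614). Adipocyte markers were lower in 3 of 10 with 0 higher, the same when adjusted over the list alone (median -0.069, camera adjusted p = 0.0195; adjusted p = 0.251 with an estimated correlation). They were lipoprotein lipase Lpl (-0.73 ± 0.054), the fatty acid carrier Fabp4 (-1.02 ± 0.083) and the receptor Pparg (-0.51 ± 0.069), which other lipid-handling cells also express. Macrophage, endothelial, lymphocyte and fibroblast marker lists did not pass camera in either comparison with Matrigel (lowest adjusted p 0.135, for endothelial markers in fibrillar collagen against Matrigel). With fry, endothelial markers passed in that comparison (adjusted p = 0.0184), and macrophage and fibroblast markers in non-fibrillar collagen against Matrigel (adjusted p = 0.0438 and 0.0345). Of the 65 named genes called in this comparison, 62 never lost the call when an array was left out.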

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

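No named gene or list that was called turned its direction under any alternative, but the balance of calls did. After quantile normalization again higher and lower calls were 640 and 612 between the collagens, 373 and 366 for fibrillar collagen against Matrigel, and 1466 and 1354 for non-fibrillar collagen against Matrigel. Of the values for named genes, 849 in the collagen comparison kept their side of the threshold, 14 gained and 269 lost the call; against Matrigel these were 1069, 25 and 123 for fibrillar and 1308, 0 and 56 for non-fibrillar collagen. For lists they were 366, 15 and 15, then 463, 19 and 22, then 460, 13 and 31. Counts of genes for fibrillar against non-fibrillar collagen (541 higher, 736 lower) were 826 and 1284 without the genes of below-median mean, where fewer genes were tested. With every probe set on its own, where more were tested, they were 219 and 257. Only 358 of the 1277 main calls (28.0%) were kept there. Counts were 84 and 84 at an adjusted p under 0.01, and 2 and 4 with a 2-fold threshold. For fibrillar collagen against Matrigel (289 and 473) they were 442 and 768, 146 and 286, 77 and 162, and 0 and 6 under the same settings, and 149 and 311 with only the 6 arrays of these groups. For non-fibrillar collagen against Matrigel (1345 and 1410) they were 615 and 804 at an adjusted p under 0.01 and 13 and 37 with a 2-fold threshold. Leaving out 1 array, with fewer arrays in the fit, gave 76 to 216 higher and 74 to 353 lower between the collagens, 134 to 261 and 219 to 457 for fibrillar collagen against Matrigel, and 823 to 1293 and 991 to 1344 for non-fibrillar collagen against Matrigel. Lists called were 0 in each comparison with an estimated correlation, against 11, 15 and 17; for non-fibrillar collagen against Matrigel they were 26 with fry and 11 after quantile normalization again, and the cause was not tested. With the replicate block, counts were 544 higher and 741 lower between the collagens. These totals are close to the main ones, but only 970 of the 1277 main calls (76.0%) were kept, and other genes took the place of the rest. Beyond the values given beside the results the block changed no other call of a named gene or list there. Against Matrigel the block gave 383 and 637 for fibrillar and 1595 and 1649 for non-fibrillar collagen. Same-numbered arrays correlated at 0.253, 0.103 and 0.0968, and at 0.125, 0.0449 and 0.135. Not every pair passed 0.1, so the numbers were not taken to pair these arrays, but a shared batch is not excluded. Signal over background was not used here, and 3 arrays per group limit the precision.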

Other observations

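The genes in these opening paragraphs were chosen after their values were seen. Cytokine genes were lower in fibrillar than in non-fibrillar collagen for Ccl2 (log2 -0.80 ± 0.160 SE, n = 3 per group), Il6 (-0.70 ± 0.124), Lif (-0.54 ± 0.103) and Ccl5 (-0.49 ± 0.068), besides Il1a, while the macrophage growth factor Csf1 was higher (0.36 ± 0.053). Their list of NF-kB targets did not pass (adjusted p = 0.166). The transmembrane glycoprotein Gpnmb was 1.60-fold higher in fibrillar than in non-fibrillar collagen (0.67 ± 0.056), and lower in both than in Matrigel (-0.69 ± 0.062 and -1.37 ± 0.062). The same order held for Cd68, at -0.55 ± 0.081 and -1.38 ± 0.081 against Matrigel. The growth factor receptor Pdgfra was higher in fibrillar than in non-fibrillar collagen (0.67 ± 0.095) and lower in the latter than in Matrigel (-1.01 ± 0.094).

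Both collagen groups had higher expression than Matrigel of the urokinase receptor Plaur (0.53 ± 0.069 in fibrillar and 0.50 ± 0.069 in non-fibrillar collagen) and the integrin chain Itga3 (0.46 ± 0.051 and 0.42 ± 0.051). Tnc was higher in both as well, at 0.75 ± 0.056 and 1.08 ± 0.056. In fibrillar collagen the laminin-binding integrin chains Itgb4 (0.43 ± 0.064) and Itga6 (0.36 ± 0.070) were higher than in Matrigel, while the receptors Sdc1 (-0.41 ± 0.041) and Itgb8 (-0.41 ± 0.091) were lower, and their list did not pass (adjusted p = 0.0683; 4 higher, 2 lower). Of 18 YAP and TAZ targets, 2 were higher in non-fibrillar collagen than in Matrigel, Ccn2 (0.87 ± 0.109) and Ankrd1 (0.85 ± 0.046), and 5 were lower, so that the list did not pass (adjusted p = 0.795). The lower ones were Tgfb2 (-0.89 ± 0.066), Fjx1 (-0.39 ± 0.071), Amotl2 (-0.38 ± 0.087), Asap1 (-0.28 ± 0.053) and Lats2 (-0.26 ± 0.066).

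Of the tests below, those on chance splits of the arrays and on liver X receptor targets as a group were set before their result was seen, and the others after. Of the 10 ways to split 6 arrays into 3 and 3, only 1, the real one, gave as many genes or lists in each comparison. Every split was fitted like the comparison itself, with the third group kept in the fit for the Matrigel comparisons. Genes called were 1277, 762 and 2755 in the real splits and 0 in every other, and lists were 11, 15 and 17 against at most 9, 9 and 10. With 10 splits this is too few to set a small p. Every other split also mixes the groups, so a difference between them, of whatever cause, widens the spread and lowers the calls. The 0 genes called there therefore do not tell an effect of the matrix from a batch. List counts were not low in every other split: camera with the preset correlation called up to 9, 9 and 10 lists. A list call with the preset correlation alone is therefore weak evidence of a difference between the groups. Mixed splits can keep part of such a difference, so the share of false list calls stays unknown.

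On the first component the fibrillar arrays lay between the other groups, and on the second they lay above both. Their position from non-fibrillar (0) to Matrigel (1) over all genes was 0.557, with 0.504, 0.565 and 0.602 for replicates 1 to 3. It was 0.534 to 0.589 leaving out 1 array. A batch of the Matrigel arrays alone would leave it near 0 if those arrays were otherwise like the non-fibrillar ones. Because both differences start from the non-fibrillar mean, 3 groups that each differ in their own way also give an intermediate position. The value therefore cannot tell a batch of the Matrigel arrays from an effect of the matrix. A mixture of the other profiles would leave few genes outside both. The fit of all 9 arrays was used here, which differs from the 6-array fit used for the collagens above. It called 149 genes outside both, 94 lower and 55 higher, and as many, 149, against both but between them. In 20 simulated mixtures at most 6 genes were outside both. Noise was drawn there for each gene separately, without the deviations that same-numbered arrays share across genes, so that range may be too narrow. Among those higher than in both were Large2 (0.84 over non-fibrillar collagen and 0.84 over Matrigel), St3gal4 (0.43 and 0.51) and Col8a1 (0.38 and 0.61). St3gal4 and Col8a1 are named outside the rule. Among those lower than in both were the interferon genes Ifit3 (-1.17 and -0.97), Gbp3 (-0.85 and -0.85) and Ifit1 (-0.95 and -0.73). Of the 94 lower genes 8 are members of the interferon list, and genes of 1 response are not separate departures from a mixture. Whether the 2755 genes that differ between non-fibrillar collagen and Matrigel reflect the matrix or another occasion cannot be told from these arrays.

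As a list, interferon genes were lower in fibrillar collagen than in both other groups, with 8 of 26 members called against both (list adjusted p = 0.207 with an estimated correlation against non-fibrillar collagen and adjusted p = 0.122 against Matrigel). Cross-hybridization within gene families would spare other members, yet the 11 outside such families were all lower than in non-fibrillar collagen, with a median of -0.237, and -0.225 against Matrigel. No single array carried the shift, since the list median nearest 0 leaving out 1 array, in either comparison, was -0.242. The order of the groups on the first component would put fibrillar collagen between the others, but the median against Matrigel was -0.278. That value is part of the pattern as it was found, so it restates the pattern and is no separate test. Whether the form of the collagen or another difference of the fibrillar arrays goes with these lower values was not tested, and interferon itself was not measured here.

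A hypothesis of this re-analysis was that Abca1 and the fatty acid synthesis genes, some of them liver X receptor targets, were higher in fibrillar than in non-fibrillar collagen as part of a wider rise of such targets. Of 19 other targets fixed for this, 14 were measured, with a median of 0.170 (0.149 to 0.184 leaving out 1 array). All 14 were positive and 6 were called, led by Abcg1 (0.63 ± 0.085) and Mylip (0.53 ± 0.070). The 12 in none of the gene lists tested above had a median of 0.160 (camera p = 1.1e-06 with the preset correlation). The test of all 14 met the criterion set beforehand, a median above 0.1 with camera p under 0.05 (camera p = 4.5e-08, and p = 0.0043 with an estimated correlation). These p-values are for 1 set and were not adjusted over lists. Unadjusted, camera with an estimated correlation gave p = 0.0099 for fatty acid synthesis and p = 0.017 for interferon. The genes that raised the hypothesis were seen in the same 6 arrays, so this is no test in new samples. Against Matrigel the median of the 14 targets in fibrillar collagen was -0.0754 (-0.109 to -0.0414 leaving out 1 array, 9 of 14 lower). For non-fibrillar collagen it was -0.246, which follows the order of the groups on the first component. Abca1 in fibrillar collagen was at 0.08 against Matrigel (adjusted p = 0.661). The fatty acid synthesis list does not by its median, at 0.119 against Matrigel (0.0841 to 0.132 leaving out 1 array). Of its 16 members 11 were positive there and 1 was called. With camera the list did not pass there with an estimated correlation (adjusted p = 0.316) or without Matrigel replicate 1 (adjusted p = 0.0626). Receptor activity was not measured here.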
